A study of Caenorhabditis elegans with 4 samples.

How the data were processed

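RNA of whole Caenorhabditis elegans animals at the L4 larval stage was compared on 4 two-colour Agilent expression arrays, each holding RNA of a mutant strain in 1 dye and RNA of the wild-type strain N2 in the other. Per the labels, 3 arrays carried the mutant sma-2(e502) and 1 array carried sma-4(e729). The genotype label of the 3 sma-2 arrays adds "x3", which the labels do not explain and which was left uninterpreted. The genes sma-2 and sma-4 encode Smad proteins, the intracellular signal carriers of the Sma/Mab TGF-beta pathway. Total RNA was made with Qiagen RNeasy columns, per the labels' protocols. The mutant RNA was in Cy5 on sma-2 replicates 1 and 3 and on the sma-4 array, and in Cy3 on sma-2 replicate 2, which the labels call the dye-flipped technical replicate. Per the file headers, replicates 1 and 2 lay on 1 slide, replicate 3 on another slide scanned on the same day, and the sma-4 array on another slide scanned on another day. Slide and genotype could therefore not be told apart for sma-4. The labels state that the sma-4 hybridisation used earlier samples again, so that its N2 RNA may be the same as that of the sma-2 arrays.

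Spot intensity values for the foreground mean and the local background median of each dye were deposited by the authors as the scanner software (Feature Extraction 9.1.3.1) wrote them, on a linear scale and not normalised, per the file headers. The same files hold a log10 ratio of Cy5 over Cy3 per spot, which the scanner software had background-subtracted and dye-normalised with 1 linear factor per dye, per the file headers. The authors' deposited value table holds a log2 ratio per spot. Set against the scanner's ratio of the same spots, its scale was log2 (slope 1 on each array), its direction was mutant over N2 on all 4 arrays, and nothing had been centred in addition: its column medians were 0.018, 0, 0.051 and 0. Used as alternatives below, the scanner's and the authors' ratios are therefore the same values and not separate support. The annotation of the arrays is that of their design, and no genome build is given in the sources used here.

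Signals were background-corrected with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 (R 4.3.3), with control spots at weight 0. Local backgrounds that the scanner software marked as outliers (between 1.26 and 3.83% of the spots of a channel, control spots included) were replaced by the channel's median, because a few very bright ones distorted the normexp fit. This repair was chosen after seeing the data, and the values without it are given with the alternatives. Spots marked as outliers themselves were left out, saturated spots were kept, and every ratio was turned to mutant over N2. The offset pulls the ratios of dim probes towards 0. The scanner's own log ratios of sma-2, which also differ in background correction and normalisation, had a slope of 1.49 on the values used here. Spots of a probe were averaged, which gave 20401 probes. A probe was kept if it was well above background in at least 1 channel on at least 2 of the 4 arrays (16559 probes), and the brightest probe stood for each gene, which left 15748 genes. Of these genes 710 had several probes, and for 1 gene the probes disagreed in sign at 1.5-fold or more. Sequence names of the files were matched to locus tags of the RefSeq gene table for assembly WBcel235, which gave the gene symbols. In all, 19057 probes matched, 564 probes carried only a probe ID, and the table's coordinates were used only for the order of neighbouring genes. Members of near-identical gene families, such as the major sperm proteins and the vitellogenins, may share signal on these probes.

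The 2 arrays of the dye swap were averaged to 1 sample, so that sma-2 had 2 samples. Labels do not state that these came from separate cultures, and p-values then measure only the spread between these samples, which may be technical. The mean log2 ratio was tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, FDR 0.05), with 1 residual degree of freedom per gene and 2.64 prior degrees of freedom. N2 RNA was in the other channel of each array, so the spread of N2 alone was not measured. Of 28 gene lists, all with at least 5 genes tested, and of 158 gene-name classes with at least 10 genes tested, the shift against all other genes was tested with camera and a preset correlation of 0.01, adjusted over lists and over classes. That correlation treats genes as nearly independent. Its p-values may be too small for families whose members may share signal, such as major sperm protein and histone genes. For the sma-4 array, which has no replicate, only values and counts are given, and the median of a list was placed among 10000 random lists of the same size matched on mean brightness in 20 bins. The difference of sma-4 and sma-2 was tested with limma on the 3 arrays with the mutant in Cy5, which assumes that the lone sma-4 array varies like the sma-2 arrays. Chance agreement of sma-2 and sma-4 through a shared N2 RNA was simulated 20 times for unchanged genes.

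The rule for named genes took the 10 largest rises and the 10 largest falls among genes past FDR 0.05 with the same sign on the 3 sma-2 arrays, 7 pathway genes in any case (6 of them tested), up to 2 highest and 2 lowest members past FDR 0.05 per list, and the 10 highest and 10 lowest genes of the sma-4 array that were well above background in both channels. Genes outside this rule are marked as chosen after their values were seen. The comparisons, the lists, the rule and most alternatives were fixed before the data were examined. Where a group was not well above background on any of its arrays, a fold is given as a bound from per-channel values after loess and Aquantile, against the lowest signal among probes well above background, which is open to dye bias. Alternatives covered background correction, normalisation, the scanner's and the authors' own ratios, filters, probe averaging, the treatment of the dye swap, leaving out each sma-2 array, variance trend, thresholds, the correlation used by camera, and 2 that were added later (local background as given, and subtraction of a dye bias estimated from the dye swap). Array number limits the precision.

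The steps were tested on simulated data with 200 changed genes among 15748. In the sma-2 comparison 66 of 69 genes with a log2 change of 1, 73 of 74 with a change of 2 and all 57 with a change of 3 were called. Another 24 unchanged genes were called, which is 10.9% of the 220 calls. In 20 runs of this simulation with different seeds, this one included, the number of unchanged genes called lay between 19 and 62 (median 30) and their share of the calls between 8.88 and 23.9% (median 13.3%), above the 5% aimed at in all 20. That share depends on how many genes change. With 4008 changed genes, whose sizes were the fitted log2 ratios of the sma-2 calls, the share in 20 runs lay between 3.56 and 6.54% (median 4.35%), above 5% in 5 of them. These runs take every sma-2 call as true and at its fitted size, which is likely too large for genes picked by their test. They therefore cannot check the share of unchanged genes among the 4008 calls. In the difference of sma-4 and sma-2 the calls were 6 of 69, 70 of 74 and 57 of 57, with 24 unchanged genes called. Since the simulated spread came from the sma-2 fit, these calls do not give the power of the real difference. Of 20 simulated lists the 5 with a shift of 0.5 were called by camera and no other was. Genes of these lists were simulated independently, so lists of genes that vary together were not checked. Figures were drawn with matplotlib 3.10.9.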

Results

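The series addresses body size regulation by the Sma/Mab TGF-beta pathway. The sma-2 arrays differed in brightness: the median signal was 7.20 and 4.03 times the local background in the mutant and N2 channels of replicate 1, 3.36 and 5.61 times in replicate 2, and 3.84 and 2.69 times in replicate 3. The sma-4 array was the dimmest, at 2.75 and 2.55 times the background. Between 65.0 and 80.0% of the spots of a channel were well above background, and at most 209 of 42964 spots were saturated. Across 15748 genes the log2 ratios of the dye-swapped arrays of the same RNA correlated with r = 0.971, and those of replicate 3 with r = 0.898 and 0.871 (genes are not independent replicates).

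The first comparison asks which transcripts differ between sma-2 mutants and wild type at the L4 stage. Transcripts of yolk proteins, sperm and oocytes were far lower in sma-2. The gene vit-1, which encodes a vitellogenin, a yolk protein precursor made in the adult intestine, fell by 4.57 ± 0.26 (SE, n = 2 samples) on the log2 scale, which is 23.7-fold. All 6 vitellogenin genes fell, among them vit-3 (-4.44 ± 0.19), vit-6 (-4.29 ± 0.15), vit-4 (-4.11 ± 0.12) and vit-2 (-4.08 ± 0.13), with a list median of -4.20 (camera, adjusted p = 8.51e-06). The adult cuticle collagen gene col-19 fell by 4.25 ± 0.06, or 19-fold. Of the 8 L4-to-adult stage markers, a list that holds col-19 and 3 of the vitellogenins, 7 fell and col-63 did not pass (list median -3.16, adjusted p = 3.39e-06). The other genes among the 10 largest falls were stha-3 (-4.45 ± 0.09), ZC373.2 (-4.11 ± 0.13), the collagen gene col-179 (-4.10 ± 0.17) and D1054.10 (-4.09 ± 0.18). Adjusted p-values of these 10 falls lay between 0.00180 and 0.00335, and each gene was lower on all 3 arrays. With an estimated correlation neither list passed (adjusted p = 0.649 for both).

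Of 75 sperm genes, 67 fell and none rose, with a list median of -1.98 (adjusted p = 1.11e-31). The lowest were the major sperm protein genes msp-31 (-3.51 ± 0.07) and msp-152 (-3.48 ± 0.08), and all 26 tested genes of the msp class fell, with a median of -3.30. As the msp genes may share signal on their probes, the p-value of the sperm list may be too small. Of 24 oocyte and eggshell genes 20 fell, with a list median of -1.54 (adjusted p = 3.29e-11). They included perm-2 (-3.29 ± 0.14) and cpg-2 (-2.86 ± 0.06), which encode eggshell components. Of 29 germ cell and meiosis genes 16 fell and none rose (median -0.43, adjusted p = 2.63e-06), led by the meiotic chromosome axis gene him-3 (-0.95 ± 0.06) and the germ granule helicase gene glh-2 (-0.79 ± 0.12). Adjusted over the list alone, 72 sperm, 22 oocyte and eggshell and 21 germ cell genes fell. With an estimated correlation none of the 3 lists passed (adjusted p = 0.649 for each), and with median centring in place of loess the germ cell list did not pass.

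Lists of furrow collagens, moulting genes, hedgehog-related and patched-related genes were shifted upward, with members that did not pass or fell. Of 6 collagens of the annular furrows of the cuticle 5 rose, among them dpy-10 (1.92 ± 0.22) and dpy-2 (1.92 ± 0.14), while dpy-3 fell (-0.83 ± 0.07), a call lost with median centring and with the scanner's log ratios. The furrow collagen median was 1.71 (adjusted p = 0.00470). Of 28 genes of collagen processing and moulting 19 rose and none fell (median 0.55, adjusted p = 1.08e-09), with sym-1 (1.82 ± 0.26) and let-653 (1.58 ± 0.13), both of the extracellular matrix of epithelia, at the top. Hedgehog-related genes rose in 17 of 51 cases and fell in 3 (median 0.08, adjusted p = 0.00339). Among them wrt-10 (1.79 ± 0.19) and wrt-1 (1.27 ± 0.06) were highest, and grl-30 (-2.33 ± 0.12) and grl-27 (-2.18 ± 0.08) lowest. Of 25 patched-related genes 11 rose and 1, ptr-24, fell (median 0.32, adjusted p = 1.22e-05), with ptc-3 at 1.01 ± 0.06. Adjusted over the list alone, 22 moulting, 18 hedgehog-related, 15 patched-related and 5 furrow collagen genes rose, and 6 hedgehog-related genes fell. The call of ptr-24 was lost with median centring, with the scanner's log ratios and with local background as given. None of these 4 lists passed with an estimated correlation (adjusted p = 0.649 for each). Whether a difference in stage between mutants and N2 lies behind these rises was not tested and stays open.

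The 154 cuticle collagens moved in both directions: 31 rose, 52 fell and 71 did not pass, or 40 and 62 adjusted over the list alone, and the list as a whole did not pass (median -0.09, adjusted p = 0.285). At its ends lay col-41 (3.54 ± 0.26) and col-90 (3.04 ± 0.22) against col-19 and col-179. The largest rise of all was that of the lipase-related gene lips-6, at 4.17 ± 0.07 or 18.1-fold. Of the next largest rises, ZK1025.3 (3.47 ± 0.13), ZK1025.5 (3.05 ± 0.18), ZK1025.2 (3.03 ± 0.16) and bah-1 (2.83 ± 0.12) lie close together in the RefSeq gene order, with gtnt-53 (0.60) between ZK1025.5 and ZK1025.3. F45D11.14 (2.66 ± 0.27), asp-12 (2.5 ± 0.24), which encodes an aspartyl protease, and adh-1 (2.45 ± 0.39), which encodes an alcohol dehydrogenase, completed the 10 largest rises. Their adjusted p-values lay between 0.00180 and 0.0253, with each gene higher on all 3 arrays. With local background as given the calls of adh-1 and ZK1025.5 were lost.

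**Figure D1:**
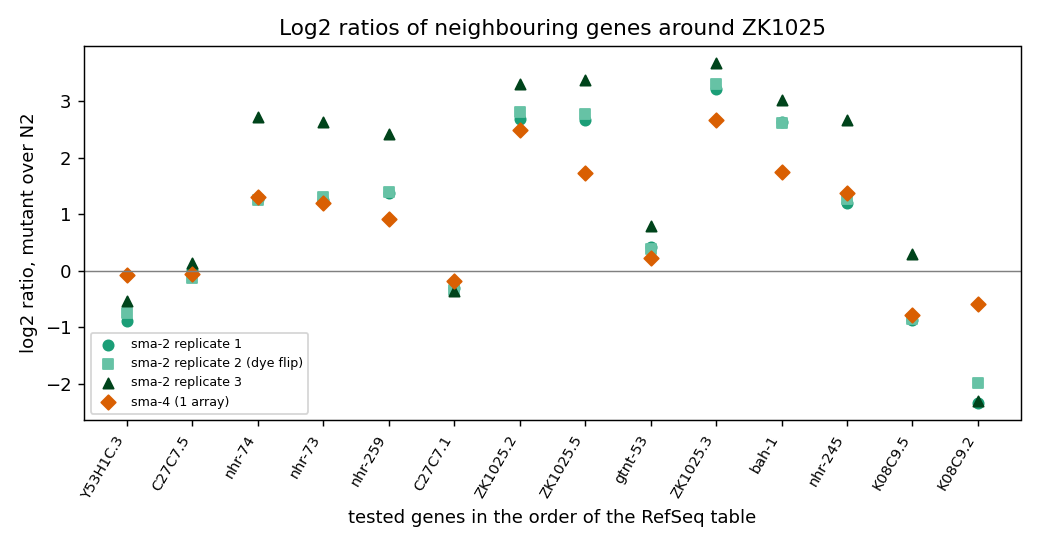
Log2 ratio, mutant over N2 (vertical axis), of tested genes in the order of the RefSeq table (horizontal axis) around the ZK1025 genes, with 1 point per array and no error bar. Of the 10 genes from nhr-74 to nhr-245, 8 lie at or above 0.92 on all arrays, while C27C7.1 lies below 0 and gtnt-53 lies between 0.23 and 0.80.

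**Figure D2:**
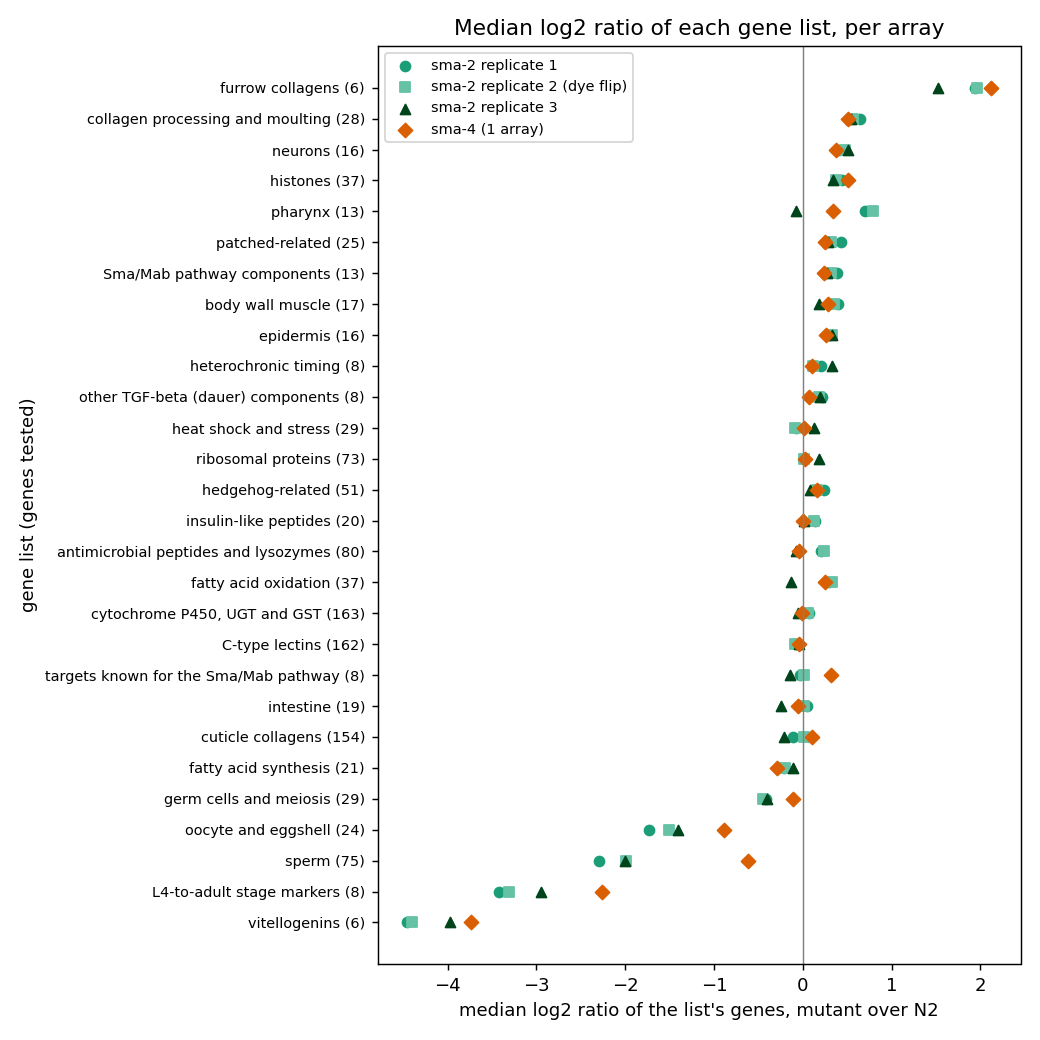
Median log2 ratio, mutant over N2 (horizontal axis), of the tested genes of each list (vertical axis, number of genes in brackets) on each array; points are single arrays with no error bar. The vitellogenin, stage marker, sperm and oocyte lists lie left of 0 on all 4 arrays, and the furrow collagens lie right of 0, between 1.53 and 2.12.

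Of the pathway's own genes, the sma-2 transcript itself did not differ detectably in the sma-2 mutant (-0.22 ± 0.15, adjusted p = 0.375), with -0.03, 0.12 and -0.48 on replicates 1 to 3. The labels do not say how the allele affects the transcript, so this value checks nothing about the strain. Among 13 tested Sma/Mab components 7 rose and 1 fell (median 0.31, adjusted p = 0.0333, counts the same when adjusted over the list alone). The body length regulator lon-1 rose by 0.67 ± 0.11 (adjusted p = 0.0264), the Smad gene sma-3 by 0.45 ± 0.07 (adjusted p = 0.025) and sma-4 by 0.47 ± 0.07 (adjusted p = 0.0245). The tetraspanin gene tsp-14 was highest (0.77 ± 0.06), and tsp-12 fell (-0.43 ± 0.06). The receptor gene sma-6 (-0.16 ± 0.07, adjusted p = 0.182) and the glypican gene lon-2 (-0.15 ± 0.07, adjusted p = 0.217) did not pass. The list was not past the threshold with the scanner's log ratios, with median centring, with probes averaged, or with an estimated correlation (adjusted p = 0.657), and the call of sma-4 was lost with the scanner's log ratios, with the dye bias subtracted and without replicate 2 (0.57, adjusted p = 0.0501). The call of tsp-12 was lost with median centring and with the scanner's log ratios.

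Of 8 genes listed as known targets of the pathway, lon-1 and mab-21 (1.02 ± 0.10) rose, and cnc-4 (-1.04 ± 0.12), an antimicrobial peptide gene of the epidermis, fell. This list did not pass (adjusted p = 0.904), its median and mean were -0.09 and -0.01 although camera ranked it upward, and 2 members fell when adjusted over the list alone. Of 8 genes in a list of other TGF-beta components, which are not all of 1 pathway, unc-129 (1.03 ± 0.07) and daf-14 (0.70 ± 0.06) rose. The median of the list was 0.23 (adjusted p = 0.0128). The call of the list was lost with median centring and with an estimated correlation (adjusted p = 0.649). The calls of cnc-4 and unc-129 were lost with local background as given.

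Several somatic marker lists were shifted upward while the intestine list was not. Of 16 neuronal genes 9 rose and none fell (median 0.51, adjusted p = 1.13e-05), led by the synaptic genes ric-4 (1.16 ± 0.09) and snt-1 (0.88 ± 0.07). Of 17 body wall muscle genes 6 rose (median 0.29, adjusted p = 0.000132), with myo-3 and hlh-1 both at 0.51 ± 0.08. Of 16 epidermal genes 7 rose and ifb-1 (-0.33 ± 0.06) fell (median 0.28, adjusted p = 0.00111), with nhr-74 (2.00 ± 0.39) and nhr-73 (1.96 ± 0.36) highest. Both nhr genes lie side by side in the RefSeq gene order, in the stretch of higher genes weighed below. Of 13 pharyngeal genes only pha-4 (0.42 ± 0.06) rose, and the list (median 0.33, adjusted p = 0.0332) had medians of 0.70 and 0.80 on the dye-swapped arrays but -0.08 on replicate 3. Its call was lost with the scanner's log ratios (adjusted p = 0.145), with the authors' ratios (0.145) and with local background as given (0.0708). Of 19 intestinal genes 2 fell, pho-1 (-0.67 ± 0.08) and ges-1 (-0.49 ± 0.09), and the list did not pass (median -0.09, adjusted p = 0.323). Of 37 histone genes 17 rose and 2 fell (median 0.39, adjusted p = 6.13e-08), with the replication-independent his-71 at 0.77 ± 0.07 and his-70 at -1.08 ± 0.10. Adjusted over the list alone, the rises were 12 neuronal, 6 muscle, 8 epidermal, 1 pharyngeal and 29 histone genes. With an estimated correlation the pharynx list had an adjusted p = 0.780 and the other lists that passed an adjusted p = 0.649. The calls of nhr-73 (1.95, adjusted p = 0.0527) and nhr-74 (2.00, adjusted p = 0.0543) were lost without replicate 2 and also with the dye bias subtracted, with local background as given and with no filter on dim probes. That of nhr-74 was also lost on 3 arrays with a dye coefficient (1.63, adjusted p = 0.0526). The fall of ifb-1 vanished with median centring (-0.00125, adjusted p = 0.998), and its call was also lost with the scanner's log ratios, with an intensity trend (adjusted p = 0.0641) and without replicate 1 (-0.33, adjusted p = 0.0518). The calls of ges-1, myo-3 and pha-4 were lost with the scanner's log ratios, those of ges-1 and pho-1 with median centring, those of ges-1 and myo-3 with local background as given, and that of myo-3 with the dye bias subtracted. Named-gene calls lost with the scanner's log ratios were also lost with the authors' ratios.

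The remaining lists did not pass, though some did under alternatives. The ribosomal list passed upward with the scanner's log ratios (adjusted p = 0.00171), the authors' ratios (0.00171), median centring (5.77e-08), local background as given (0.000118), the dye bias subtracted (0.00757) and without replicate 1 (0.0221). The heat shock list passed upward with median centring (adjusted p = 0.00715), the lectins downward with median centring (0.0198) and the dye bias subtracted (0.0486), and fatty acid synthesis downward with no filter on dim probes (0.0492) and on 3 arrays without a dye coefficient (0.0484). Of 162 C-type lectins 33 fell and 5 rose (adjusted p = 0.0698), from clec-87 (-2.86 ± 0.12) to clec-230 (1.80 ± 0.11). Of 80 antimicrobial peptide and lysozyme genes 10 rose and 11 fell (adjusted p = 0.464), with cnc-3 (0.99 ± 0.14) and spp-17 (-1.81 ± 0.07) at the ends. Of 21 fatty acid synthesis genes 5 fell (adjusted p = 0.0840), with the elongase genes elo-5 (-1.10 ± 0.07) and elo-6 (-0.78 ± 0.07) lowest. Of 37 fatty acid oxidation genes 4 rose and 6 fell (adjusted p = 0.705), including acs-2 (1.42 ± 0.14), acdh-8 (-2.23 ± 0.06) and acdh-5 (-1.96 ± 0.07). Of 8 heterochronic timing genes 3 rose (adjusted p = 0.0780), among them lin-29 (0.52 ± 0.08). Of 163 cytochrome P450, UGT and GST genes 11 rose and 21 fell (adjusted p = 0.768), with ugt-13 at 1.26 ± 0.13 and ugt-47 at -1.70 ± 0.11. Of 29 heat shock and stress genes 1 rose and 2 fell (adjusted p = 0.181), of 20 insulin-like peptide genes 2 rose and 2 fell (adjusted p = 0.345), and of 73 ribosomal protein genes 5 rose and 2 fell (adjusted p = 0.0840). The insulin-like gene ins-31 was not well above background in sma-2 on any array and was at least 2.28-fold lower there. The call of ins-31 was lost with local background as given, that of elo-6 with median centring (-0.45, adjusted p = 0.117) and that of lin-29 with the scanner's log ratios (adjusted p = 0.0503). Medians and means differed in sign for the antimicrobial, fatty acid oxidation, cytochrome P450 and insulin-like lists. Adjusted over the list alone, the counts of rises and falls were 5 and 32 for the lectins, 10 and 11 for the antimicrobial genes, 0 and 5 for fatty acid synthesis, 5 and 6 for fatty acid oxidation, 4 and 0 for timing, 11 and 21 for cytochrome P450 and relatives, 1 and 2 for stress, 1 and 2 for insulin-like peptides, 0 and 1 for ribosomal proteins, and 0 and 1 for the intestine.

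In the search over 158 gene-name classes, 24 were shifted, 20 upward and 4 downward. Downward were the sperm classes msp (adjusted p = 5.88e-21) and spe (25 of 31 genes fell, adjusted p = 1.53e-11), the trypsin-like proteases try (7 of 13 fell) and cdc (5 of 16 fell). Without replicate 2 the calls of try (adjusted p = 0.0623) and cdc (0.05005) were lost, and that of cdc also with median centring (0.602) and the strict filter (0.104). Among the upward classes were the neuropeptide classes flp (15 of 29 rose, median 0.51, adjusted p = 4.04e-07) and nlp (18 of 63 rose, adjusted p = 5.73e-05), the nuclear hormone receptors nhr (36 of 197 rose, adjusted p = 1.51e-06), unc (32 of 86 rose, adjusted p = 2.42e-09) and bus (9 of 14 rose, adjusted p = 7.59e-06). None passed with an estimated correlation (smallest adjusted p = 0.995).

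Altogether 4008 of 15748 genes (25.5%) passed FDR 0.05, 1524 higher and 2484 lower in sma-2, and 4005 of them had the same sign on the 3 arrays. Of these genes 214 were at least 2-fold higher and 968 at least 2-fold lower. The share of higher genes among the calls was 38%, against 49.3% with the scanner's log ratios and 54.2% with median centring. Ratios of dim genes were compressed: the scanner's log ratios were 5.68 for lips-6, 4.14 for ZK1025.5, -5.13 for stha-3 and -5.08 for D1054.10, and the sperm list had a median of -2.80 there.

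The second comparison sets sma-4 mutants against wild type, on 1 array without a replicate. The vitellogenins were again lowest, with vit-1 at -4.62, vit-3 at -4.46, vit-4 at -3.91, vit-2 at -3.56, vit-6 at -3.55 and vit-5 at -3.54. C10G8.4 (-3.15), stha-3 (-3.09), pud-3 (-3.08) and T22B7.7 (-3.03) completed the 10 lowest. The highest were col-41 (4.10), asp-12 (3.87), adh-1 (3.82), ech-9 (2.82), lips-6 (2.71), ZK1025.3 (2.66), wrt-10 (2.52), ZK1025.2 (2.49), dpy-7 (2.45) and col-90 (2.43). The sma-4 transcript had a log2 ratio of -0.37 on this array, and lon-1 was at 0.82. In all 199 genes were at least 2-fold higher and 212 at least 2-fold lower. With median centring 67.1% of such genes were higher, against 48.4% here, and the scanner's log ratios gave 2043 such genes, 61.7% of them higher.

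On the sma-4 array 19 of the 28 lists had a median outside the central 95% of random lists, 13 above and 6 below. Above lay the furrow collagens (median 2.12), collagen processing and moulting (0.51), histones (0.51), neurons (0.38), pharynx (0.34), targets known for the pathway (0.31), body wall muscle (0.29), epidermis (0.26), patched-related genes (0.25), fatty acid oxidation (0.25), Sma/Mab components (0.24), hedgehog-related genes (0.16) and cuticle collagens (0.10). Below lay the vitellogenins (-3.73), stage markers (-2.27), oocyte and eggshell genes (-0.88), sperm genes (-0.62), fatty acid synthesis (-0.29) and C-type lectins (-0.04). The Sma/Mab list lay inside with the scanner's log ratios, the authors' ratios and probes averaged. The ribosomal list lay above with the scanner's and the authors' ratios and median centring, and the cytochrome P450 list below with these and with the strict filter. The antimicrobial list lay below without background subtraction, with probes averaged and against random lists from all genes, and the germ cell list below against random lists from all genes and with the dye bias subtracted. These percentiles describe this array and are no test.

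The log2 ratios of sma-4 and of sma-2 correlated across genes with r = 0.732 and rho = 0.724. Per sma-2 array r was 0.769 for replicate 1, 0.759 for the dye-flipped replicate 2 and 0.648 for replicate 3. Unchanged genes whose N2 RNA was shared with the dye-swap pair gave a simulated r of 0.348, and 1 N2 RNA on all arrays gave 0.574. The covariance was 0.160, against simulated values of 0.00468 and 0.00938. Both simulations took the spread of N2 from that between the sma-2 samples. An N2 RNA common to all arrays adds nothing to that spread. How much of the correlation and covariance came from a shared N2 RNA therefore cannot be told. Of the 214 genes past FDR 0.05 and at least 2-fold higher in sma-2, 98 were at least 2-fold higher on the sma-4 array, where independent lists would share 2.70. Of the 968 lower genes 152 were at least 2-fold lower there, against 13, and 1 gene was 2-fold changed in opposite directions. The counts for independent lists take no account of N2 RNA shared between arrays.

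**Figure D3:**
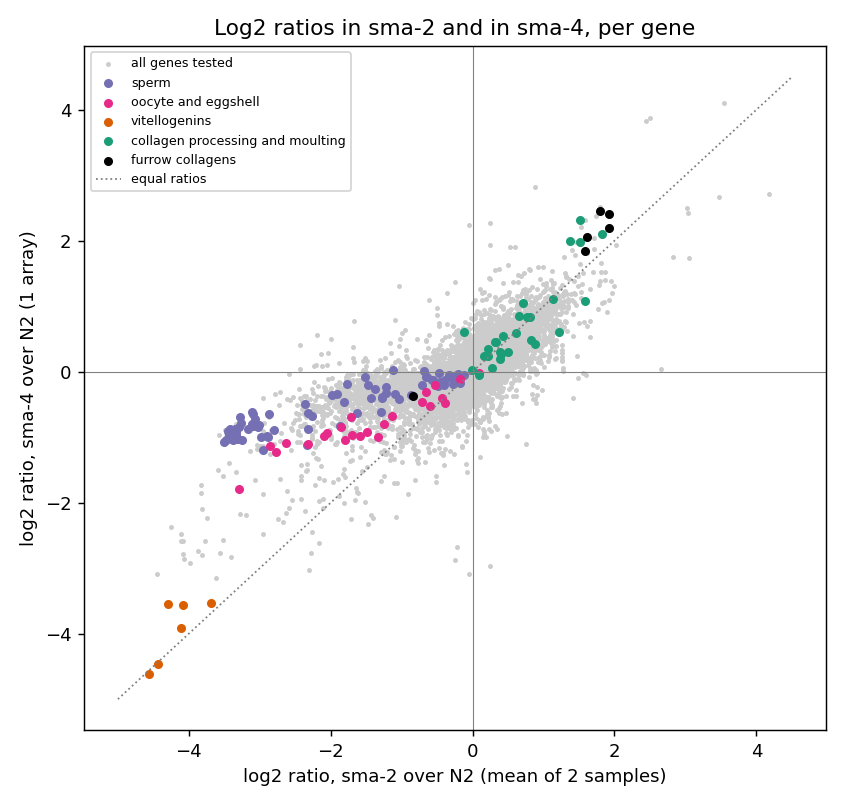
Log2 ratio over N2 of each tested gene in sma-2 (horizontal axis, mean of 2 samples) and in sma-4 (vertical axis, 1 array), with 5 gene lists in colour and a dotted line of equal ratios. Vitellogenins lie close to the line, with medians of -4.20 and -3.73, while sperm genes lie far above it, with medians of -1.98 and -0.62.

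Whether sma-4 differed from sma-2 was tested on the 3 arrays with the mutant in Cy5. With limma no gene passed FDR 0.05 (smallest adjusted p = 0.0636), and 1996 genes had an unadjusted p under 0.05. The smallest p-values belonged to col-88, at 0.41 on the sma-4 array against -2.39 and -2.33 in sma-2, and to sperm genes such as msp-113, at -0.88 against -3.46 and -3.48 (genes chosen after their values were seen). With the sma-2 samples as in the first comparison 369 genes passed, 362 of them higher in sma-4, and without background subtraction 375 passed. Log2 differences as large as 2.77 for col-88 and 2.59 for msp-113 were not called in the test on 3 arrays. Its lack of calls therefore does not show that large differences are absent. Hybridisation date and genotype cannot be told apart in this difference.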

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

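No test was run for this part after the results were seen. The differences given here were picked out by their signs and were not tested singly, and in the limma test of sma-4 against sma-2 no gene passed. In 3 of the named genes the log2 ratios had 1 sign on every sma-2 array and the opposite sign on the sma-4 array. The sma-4 transcript had log2 ratios of 0.74, 0.35 and 0.40 in sma-2 mutants and of -0.37 in the sma-4 mutant. The antimicrobial peptide gene cnc-4 had -1.0, -0.69 and -1.23 in sma-2 and 1.31 in sma-4. The intermediate filament gene ifb-1 had -0.35, -0.32 and -0.33 in sma-2 and 0.071 in sma-4, which is close to 0, and with median centring its sma-2 value was -0.00125.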

How the results depend on the processing

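Local background as given and the subtracted dye bias were added after seeing the data. The sma-4 array had the lowest signal over background (2.75 and 2.55). The sma-2 count of 4008 genes lay between 2683 (local background as given) and 5601 (FDR 0.10) under all alternatives but these: 3 arrays without a dye coefficient gave 6797, and a 2-fold minimum in addition gave 1182. Fitting 3 arrays without a dye coefficient counts the dye-flipped technical replicate as a sample of its own, so 6797 is no like count. How far this accounts for the rise was not tested. With a dye coefficient the 3 arrays gave 4769. Without replicate 1 or 2 it was 3633 to 3768, with 17 to 16 lists and 24 to 23 classes. Lists and classes numbered 15 to 18 and 19 to 31, but 0 and 0 with an estimated correlation, which rests on 1 residual degree of freedom. The sma-4 count of 411 became 620 without background subtraction, 2043 with the scanner's and 2045 with the authors' ratios, 1349 at 1.5-fold and 121 at 3-fold. The scanner's and the authors' ratios have no offset but also differ in background correction and normalisation, so the part of the offset was not isolated. The difference of sma-4 and sma-2 gave 375 genes without background subtraction and 369 with the dye swap averaged, and 0 otherwise; the cause was not tested. The correlation of sma-2 and sma-4 stayed between 0.692 and 0.770. Of 1512 tested values of 101 named genes in sma-2, 1417 kept their side of the threshold and direction, 84 lost and 6 gained the call, and 5 changed sign. This tally counts the scanner's ratios again as the authors' ratios. It also counts Aquantile normalisation, which leaves the ratio of each probe unchanged. It therefore overstates the stability across separate settings. Without replicate 3, where there is no test, 100 of 101 kept their direction. For named genes that changed call or sign with median centring, the limma adjusted p followed the size of the ratio and not the spread of the samples. T22B7.7 had an SD of 1.95 between the sma-2 samples and an adjusted p of 0.105 in the main fit. With median centring it was at -2.33 with an adjusted p of 8.05e-27. Calls lost with median centring are therefore not comparable gene by gene with the main test. The values that changed sign were pud-3 (0.0109 with the scanner's and 0.0108 with the authors' ratios, 0.26 with median centring, and from -1.69 to 0.030 without 1 of the replicates), rpl-11.1 (0.13 with median centring) and sma-2 (from -0.25 to 0.044 without 1 of the replicates); the cause was not tested. A random block for the dye swap or slide could not be fitted, since 1 pair gives no estimate of the correlation. Without replicate 3 only 1 sample remains and no test, and likewise for the difference without replicate 1 or 3. Mutant and N2 are paired on each array by the ratio itself. No paired analysis was possible for sma-4 against sma-2, because the 1 sma-4 array lay on another slide scanned on another day. Replicate numbers do not pair arrays across the genotypes.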

Other observations

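The tests of early-embryo genes, of gene runs and of a gain or loss of a stretch of genome were written before their results were seen. The gain or loss test was written for the region of the longest run and was then applied to the stretch from nhr-74 to nhr-245. The tests of oocyte against sperm genes, germ-line share, dye bias, loss from N2 and compression, the scanner ratios of the early-embryo genes and the runs of genes past FDR 0.05 were chosen after. Of the oocyte against sperm test, the sma-4 values of sperm genes and vitellogenins had been seen and those of oocyte genes had not.

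Of the heat shock genes, 5 differed between the samples of sma-2 by more than 4-fold (genes in this paragraph were chosen after their values were seen). On replicate 3 the log2 ratios over N2 were 2.18 for hsp-16.1, 1.80 for hsp-16.2, 1.98 for hsp-16.41, 2.01 for hsp-16.48 and 2.12 for hsp-70, against -0.40, -0.85, -0.27, -0.20 and -0.36 in the dye-swap pair and -0.48, -0.64, -0.42, -0.35 and -0.42 on the sma-4 array. The chaperone genes hsp-1 (0.16 on replicate 3), hsp-6 (0.14) and hsp-90 (0.15) stayed close to 0 there, while hsp-110 had 0.66 there and -0.16 in the pair. Also close to 0 there were hsp-16.21 (0.10), hsp-16.20 (-0.01) and hsp-4 (0.14). The fixed list of heat shock and stress genes did not pass in sma-2. The gene pud-3 ran from -1.69 in the pair to 1.59 on replicate 3, with pud-4 at -1.16 and 1.66, and they had -3.08 and -2.97 on the sma-4 array. The acyl-CoA dehydrogenase gene acdh-1 went the other way, with 0.95 in the pair and -1.92 on replicate 3. In all 201 genes lay at least 2-fold apart between the pair and replicate 3.

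The first pattern weighed is the joint fall of sperm, oocyte, vitellogenin and adult collagen transcripts. Dye bias is argued against, since the median of these lists on the dye-flipped array was 1.01 times that on replicate 1. The medians of 5 somatic lists lay 0.60 apart (permutation test with 100000 exchanges of genes, p = 0.00011). This argues only against an equal rise of all 5 lists through a smaller share of germ-line RNA, and the permutation treats genes as independent. The intestine list was lowest (-0.09), while epidermis (0.28), body wall muscle (0.29), pharynx (0.33) and neurons (0.51) were all higher. A smaller germ-line share behind the rises of those higher lists stays open and was not tested. Embryos or gravid adults among the N2 animals stay open. The median of 7 early-embryo genes (-0.079, quartiles -0.46 to -0.04) met the bound of -0.5 written beforehand against them. Of the 7 genes 6 were well above background in N2 on 3 or more arrays. Still, 5 of the 7 lay near the floor, taken as a mean log2 brightness under 7, where the median over all genes was 7.27. Those above it, sdz-24 (-0.68, limma adjusted p = 0.0561) and end-3 (-0.37, 0.127), did not pass but were lower on all 3 sma-2 arrays. Near the floor tbx-38 passed (-0.55, limma adjusted p = 0.0473), and the rest lay between -0.079 and -0.011 (genes chosen after their values were seen). In the scanner's log ratios of the 7 genes (median -0.20) the lower quartile of -0.62 crossed the bound. The floor and the scanner's quartile were weighed, with changes of the verdict, only after the values were seen. Embryos or gravid adults in N2 cannot be told apart from an effect of the genotypes on the genes of this pattern or on the rate of development. The same holds for a collection of the mutants at an earlier point of development than N2. In N2 the mean log2 signals of col-19 and vit-1 on the sma-2 arrays were 15.1 and 14.1. Both transcripts were thus bright in N2 animals labelled L4, which does not tell these explanations apart. The sma-4 array kept a smaller share of the sma-2 fall in sperm genes (0.313) than in oocyte genes (0.575), a difference of 0.26 (95% bootstrap interval over genes 0.17 to 0.46), but mutants that were equally early would give equal shares, and 1 sma-4 array decides nothing.

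The second pattern is that of neighbouring genes that were higher together. There were 3 runs of at least 4 adjacent tested genes that were all 2-fold higher in sma-2, such as lpr-3 (1.71), lpr-6 (1.61), lpr-5 (1.74) and lpr-4 (1.58), more than chance placement gives (permutation p = 1e-05, the smallest that 100000 shuffles can give). The run of dyf-4 holds F45D3.4, which did not pass (1.26 ± 0.43, adjusted p = 0.122), and 2 runs were left among genes past FDR 0.05 (permutation p = 1e-05). The stretch from nhr-74 to nhr-245 holds none of these runs, because C27C7.1 (-0.34) and gtnt-53 (0.60) interrupt it. The run tests therefore do not cover this stretch. In it 8 of 10 tested genes were at least 2-fold higher in sma-2. All 8 were well above background in N2 on 3 or more arrays, which argues against a loss of the stretch from the N2 animals. A gain of the stretch in the mutants cannot be told apart from shared regulation. The bound written beforehand named the region of the longest run and not this stretch. By that bound a gene within 0.3 of 0 would speak against a gain, and the nearest, C27C7.1, lay at 0.34 from 0. But C27C7.1 was lower (-0.34 ± 0.06), and that both signs leave the question open was decided after the values were seen. Signal shared by related sequences may also contribute and was not tested.

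The third pattern is that, over the genes past FDR 0.05 in sma-2, the slope of sma-4 on sma-2 log2 ratios was 0.453. These genes were chosen by their sma-2 values, which lowers the slope, and genes with a smaller ratio in sma-4 were not counted. Some ratios lay further from 0 in sma-4, such as col-41 (4.10 against 3.54), asp-12 (3.87 against 2.5), adh-1 (3.82 against 2.45), elo-5 (-1.69 against -1.10) and the furrow collagen median (2.12 against 1.71). Compression of the dim sma-4 array by the offset is argued against as the whole cause: with the scanner's log ratios, which have no offset, the slope was 0.481. The genotype, the stage of the animals and the hybridisation date stay open for this pattern and were not tested.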
